A study of Rattus norvegicus with 12 samples.

How the data were processed

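Right ventricular papillary muscles of 12 male rats, 1 muscle per animal, formed 4 groups of 3 with high or low mean stretch and high or low cyclic shortening. From 100 ng of total RNA per muscle, labelled RNA was hybridized to Affymetrix expression arrays. The deposited value table holds log2 intensities that the authors normalized by RMA per the submitters' processing notes; the version of RMA was not stated. A deposited filtered table holds 16391 of the 31099 probe sets, with log2 values identical to those of the full table (largest difference 0). Its header names an intensity of 50 (log2 5.64); tested on the values, the probe sets kept are those above it on at least 2 arrays of any 1 group, with 0 missing and 0 extra.

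Of 31042 probe sets that were not controls, 20826 carried 1 gene symbol in the table of probe genes, 436 several and 9780 none; 20758 of those with 1 symbol were matched by gene number to the RefSeq table of the rat assembly GRCr8, which changed 0 symbols. Probe sets whose mean over all arrays was under the 40th percentile (4.91) were removed, which left 18625, of which 13789 had 1 symbol. Each of 10316 genes was represented by its probe set with the highest mean; 2626 genes had more than 1 past the filter. Limma (version 3.58.1, in R 4.3.3) was fitted with a mean per group and empirical Bayes moderation, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Contrasts were the main effects of stretch and shortening, their interaction, each input at each level of the other, and a moderated F-test. Values are log2 differences with moderated standard errors. Replicate numbers were checked for pairing: residuals of 18 pairs of the same number in different groups had r of -0.195 to 0.296, with a mean of 0.00721 against -0.00285 for other pairs, and were treated as unpaired. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

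The 41 gene lists, the 16 genes followed whatever their values, the contrasts and the first set of alternatives were fixed before the data were examined. Lists with at least 5 tested genes, 35 in all, were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were run beside it. The list of the cytosolic ribosome was fixed as a pattern of symbols that also takes in ribosomal S6 kinases, and glycolysis and hypoxia share Adm and Vegfa with growth factors and paracrine signals. Other lists share genes as well, such as Tnni3 and Myl2 in sarcomere and in cardiomyocyte markers. Genes were named by a rule: among called genes the 10 largest rises and 10 largest falls of each main effect, the 5 and 5 largest for other contrasts, the 5 smallest p-values where fewer than 5 genes passed, and up to 4 genes of smallest adjusted p from each list described.

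Alternatives were no filter, the filtered table, every probe set, the mean of the probe sets of a gene, repeated quantile normalization, a trended robust prior, no moderation, array weights, the replicate number as a block, weight, age or the 3' to 5' index of the Gapdh and Actb controls as a covariate, a threshold of 0.1, a minimum of 1.5-fold, and leaving out each array. Added after the data were seen were fits without the low-low group, the lists at a single level of the other input, the contrasts of the low-low group with the other 3 and between the groups with a single high input, the raising of array values under the filter to it, and the Local Pooled Error test named in the header of the filtered table, in an implementation written from its description. The precision is set by the number of arrays. On simulated data of 10316 genes with planted changes, stretch at high shortening recovered 26.9% of changes of 1.41-fold, 82.1% of 2-fold and 98.5% of 4-fold, with 8 calls among unchanged genes; the stretch main effect recovered 56.7%, 92.5% and 100% (12 such calls) and the interaction 7.46%, 47.8% and 95.5% (4 such calls). Chance was tested with 100 splits of the arrays, the real one and others drawn at random (seed 1). Comparisons of 2 groups used all 10 splits, the real one included. Probe sets without a symbol or with several were left out of the gene counts; positions of probes on transcripts were not given in the sources used here.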

Results

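Messenger RNA was measured in 12 right ventricular papillary muscles, small columns of heart muscle that anchor the tricuspid valve. Each muscle came from a different male LBNF1 rat and was paced at 1 Hz at 37 °C for 12 h in culture. Mean stretch was set to a target of 16% or 4% of slack length, and cyclic shortening to a target of 16% or 4%. This gave 4 groups of 3 muscles: high stretch with high shortening, high stretch with low shortening, low stretch with low shortening (the low-low group below), and low stretch with high shortening. The arrays gave a log2 intensity for 31042 probe sets besides 57 controls, and 10316 named genes were tested. Median log2 intensity per array lay between 5.52 and 5.57. The number of arrays limits the precision: the median 95% confidence interval of a difference between 2 groups reached 0.33 log2 (1.26-fold) to either side.

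The 3 arrays of the low-low group stood apart from the other 9. Across probe sets, which are not independent replicates, Pearson's r was 0.986 to 0.989 among those 3 arrays, 0.974 to 0.994 among the other 9 and 0.918 to 0.933 between the sets. Among the other 9, median r was 0.982 within groups and 0.985 between groups. The first principal component held 66.6% of the variance and the second 7.09%. Control probe sets of Gapdh, a glycolytic enzyme, and of Actb, cytoplasmic actin, read the 3' and the 5' end of their transcripts. The 3' signal of Gapdh exceeded the 5' signal by 0.54 ± 0.21 log2 (SD, n = 3) in the low-low group and by 2.94 ± 0.60 log2 (SD, n = 9) in the other arrays. For Actb the excess was 2.19 ± 0.37 and 3.68 ± 0.49 log2 (SD). The mean of both, called the 3' to 5' index below, was 1.36 ± 0.29 in the low-low group. It was 2.94 ± 0.32 with high stretch and high shortening, 3.77 ± 0.63 with high stretch and low shortening, and 3.21 ± 0.045 with low stretch and high shortening (SD, n = 3 each). Labelled animal weight, whose unit was not stated, was 311 ± 6.51 (305 to 318) in the low-low group and 280.3 ± 10.5 (267 to 297) elsewhere. The spread of log2 values within an array was also wider, with a mean SD of 2.41 against 2.34. In exact two-sided permutation tests of these arrays, chosen after their separation was seen, each of these 5 quantities gave p = 0.00455 (n = 3 and 9, Benjamini-Hochberg adjusted p = 0.00545), the smallest p that the permutations can give. Labelled age was the sixth quantity: 75 in all 3 animals of the low-low group and 80.1 ± 4.37 (72 to 85) in the others, with an exact permutation p = 0.109.

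**Figure D1:**
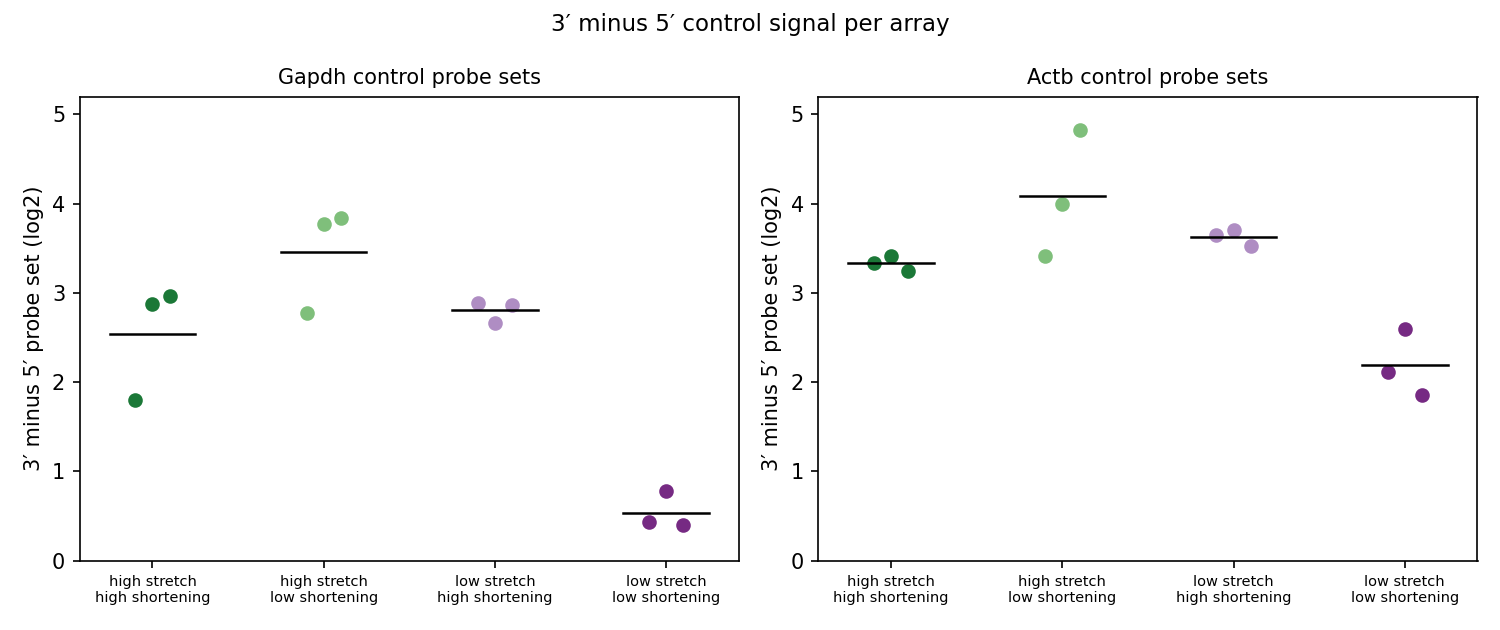
Difference between the 3' and the 5' control probe sets (log2) of Gapdh and of Actb on each of the 12 arrays, by group; dots are arrays and lines are group means. For Gapdh the low-low group averaged 0.54 and the other 9 arrays 1.79 to 3.83.

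The effect of mean stretch, averaged over both levels of shortening, was read as the mean of the high-stretch groups minus that of the low-stretch groups. Among the genes lower at high mean stretch was Pfn1, the actin-binding profilin 1, which changed by -2.20 log2 (SE 0.12, n = 12, adjusted p = 6.84e-07). Cd36, a fatty acid transporter, changed by -1.84 (SE 0.14) and Higd2a, an assembly factor of the respiratory chain, by -1.89 (SE 0.08). Among the genes higher at high stretch were Ube3al1 at 1.76 (SE 0.10) and Dhx36, a helicase of folded RNA and DNA, at 1.72 (SE 0.08). Some large changes were measured from dim signal. Fabp4, a fatty acid-binding protein of capillary endothelium and adipocytes, changed by -2.86 (SE 0.17, adjusted p = 6.84e-07), or by -2.26 when array values under the intensity filter of 4.91 log2 were raised to it. Hira, a histone chaperone, changed by 1.91 (SE 0.14, adjusted p = 2.36e-06), or by 1.25 with values so raised. Of the genes named next, Cxcl6, Med30, Id3, Ryr3 and Tmc4 were also under that value in at least 1 group, and gave -1.73, -1.54, -1.59, 1.19 and 1.07 so raised. Among the 10 largest falls were also Atp5mg (-2.21), Ndufb8 (-1.97), Cxcl9 (-1.93), Med30 (-1.91), Cxcl6 (-1.83) and Id3 (-1.81). Among the 10 largest rises were also Wdfy1 (1.72), Ankrd11 (1.67), Kpna1 (1.59), Slc16a6 (1.57), Ryr3 (1.49), Gnb1 (1.47) and Tmc4 (1.41). The calls of Slc16a6 (1.42, adjusted p = 0.0712) and Ryr3 (1.38, adjusted p = 0.130) ended with the 3' to 5' index as a covariate. Ryr3 also differed at high shortening (0.97, or 0.69 with values so raised), without passing, against 2.02 at low shortening. In Fabp4 and Hira, given as examples, the difference lay in the low-low group. Fabp4 averaged 9.43 ± 0.54 log2 there and 3.81 ± 0.06, 3.83 ± 0.14 and 3.93 ± 0.37 with high stretch and high shortening, high stretch and low shortening, and low stretch and high shortening (SD, n = 3 each). Hira averaged 3.59 ± 0.24 there against 7.66 ± 0.28, 7.51 ± 0.19 and 7.76 ± 0.34 in the same order. In all, 3627 genes passed in limma (1459 higher and 2168 lower at high stretch, 222 by at least 2-fold). After repeated quantile normalization 1821 were higher and 1816 lower. At an unadjusted p under 0.05 there were 4619, against 515.8 expected by chance. Of the 3627 stretch calls, 3554 (98.0%) also passed between the low-low group and the other 3, all with the opposite sign. The stretch contrast subtracts the low-low arrays. With the low-low group left out, a fit chosen after the data were seen, stretch was read at high shortening only. Limma then called 0 genes, with 304 at an unadjusted p under 0.05, and a Local Pooled Error test of the same 2 groups called 10 probe sets.

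Of the gene groups fixed beforehand, 10 moved with mean stretch, each downward relative to the other genes. In oxidative phosphorylation, 52 of 76 tested genes fell and 1 rose (camera adjusted p = 9.37e-13, and adjusted p = 0.352 with an estimated correlation). Ndufa5, a subunit of complex I, changed by -1.59 (SE 0.07), Ndufb10 by -1.13 and the ATP synthase subunit Atp5pf by -1.06. In the mitochondrial ribosome 39 of 73 genes fell and 11 rose (Mrps18b -0.94, Mrpl54 -0.92, adjusted p = 4.82e-05, and adjusted p = 0.633 with an estimated correlation). In fatty acid oxidation 20 of 34 fell and 1 rose (Hadha -0.78, Acads -0.66, Etfb -0.52, adjusted p = 5.38e-05, and adjusted p = 0.547 with an estimated correlation). In glycolysis and hypoxia 19 of 37 fell and 4 rose (Slc2a4, the muscle glucose transporter, -1.63, Pgam2 -1.10, Gpi -0.80, adjusted p = 0.00619, and adjusted p = 0.352 with an estimated correlation). Inflammatory genes fell as well. Of 41 cytokines and chemokines 21 fell and 1 rose (Nfkbia -1.32, Ccl7 -1.26, Il1b -0.92, median -0.64, adjusted p = 5.38e-05, and adjusted p = 0.657 with an estimated correlation). In the interferon response 12 of 23 fell and none rose (Gbp2 -1.48, Psmb9 -1.26, Cd74 -0.85, adjusted p = 0.000616, and adjusted p = 0.725 with an estimated correlation). In the proteasome 17 of 33 fell and 3 rose (Psmd6 -1.01, Psmb1 -0.73, adjusted p = 0.000764, and adjusted p = 0.547 with an estimated correlation). In oxidative stress and NRF2 13 of 27 fell (Txnrd1 -0.95, Sod2 -0.76, adjusted p = 0.00619, and adjusted p = 0.352 with an estimated correlation). In the cytosolic ribosome 19 of 53 fell and 6 rose (Rps24 -1.75, Rpl24 -1.25, adjusted p = 0.0168, and adjusted p = 0.850 with an estimated correlation). Of 17 cardiomyocyte markers 9 fell (Tnni3 -0.54, Myl2 -0.46, adjusted p = 0.0344, and adjusted p = 0.352 with an estimated correlation). With the 3' to 5' index as a covariate the calls of Il1b (-0.76, adjusted p = 0.0976) and Txnrd1 (-0.41, 0.205) ended, and with the mean of probe sets that of Myl2 (-0.22, 0.0509).

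Adjusted over the list alone, the falls among these 10 groups numbered 52 in oxidative phosphorylation, 41 in the mitochondrial ribosome, 21 in fatty acid oxidation, 20 in glycolysis and hypoxia, 21 in cytokines and chemokines, 12 in the interferon response, 17 in the proteasome, 13 in oxidative stress and NRF2, 21 in the cytosolic ribosome and 9 in cardiomyocyte markers. Without the low-low group, only the interferon response, of these 10, passed (Down, adjusted p = 0.00105), but not with an estimated correlation (0.865) or by fry (0.989). That call also ended without high stretch high shortening replicate 2 (0.293) or low stretch high shortening replicate 1 (0.284). Oxidative phosphorylation lay upward there at an adjusted p of 0.522. The calls of the cytosolic ribosome and of the cardiomyocyte markers ended when quantile normalization was applied again (adjusted p = 0.542 and 0.571). The cytosolic ribosome also turned upward with the 3' to 5' index as a covariate (adjusted p = 0.999), which ended the calls of oxidative stress and NRF2 (0.486) and the proteasome (0.0529) as well. For cardiomyocyte markers the call ended with weight as a covariate (0.086), in the authors' filtered table (0.0603), without high stretch low shortening replicate 1 (0.0765) and without low-low replicate 1 (0.0518). For the cytosolic ribosome it ended without high stretch high shortening replicate 3 (0.0543) and without low stretch high shortening replicate 3 (0.0516). The low-low arrays that set these shifts are those with the low Gapdh 3' excess of 0.54 log2 and the labelled weight of 311.

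The effect of cyclic shortening, averaged over both levels of stretch, was read as the mean of the high-shortening groups minus that of the low-shortening groups. Among the genes lower at high shortening was Mif, a macrophage cytokine, which changed by -1.76 (SE 0.08, n = 12, adjusted p = 1.58e-07). Fabp4 changed by -2.76 (SE 0.17, adjusted p = 1.05e-06), or by -2.26 with values under 4.91 log2 raised to it. Ccn1, a signal bound to the matrix, changed by -1.80 (SE 0.22, adjusted p = 0.000128) and the neutrophil chemokine Cxcl6, dim in 3 groups, by -1.78 (SE 0.18), or by -1.69 with values so raised. Rises included Hira at 2.16 (SE 0.14, adjusted p = 1.49e-06) and Nek1, a kinase of cilia and DNA repair, at 1.66 (SE 0.08, adjusted p = 3.51e-07). With values so raised these were 1.5 and 1.12, and Drg1 and Retreg3, named next, gave -1.72 and 1.58. The other large falls were in Ndufb8 (-1.89), Pfn1 (-1.87), Atp5mg (-1.86), Drg1 (-1.84), Higd2a (-1.83) and Cd9 (-1.75). The other large rises were in Slc16a6 (1.70), Ube3al1 (1.68), Retreg3 (1.63), Dnajc7 (1.56), Thoc3 (1.51), Dhx36 (1.49), Slc3a1 (1.47) and Ankrd11 (1.41). Ccn1 averaged 11.32 ± 0.30 log2 in the low-low group against 8.04 ± 0.60 with high stretch and high shortening, 8.53 ± 0.57 with high stretch and low shortening, and 8.22 ± 0.23 with low stretch and high shortening (SD, n = 3 each). In limma 3450 genes passed (1602 higher and 1848 lower at high shortening, 176 by at least 2-fold). Repeated quantile normalization turned this balance, with 1853 higher and 1587 lower. Of the 2511 genes called for both stretch and shortening, 2509 moved the same way. Both contrasts subtract the low-low arrays, so a shift of that group by itself gives both the same sign. Of the 3450 shortening calls, 3367 (97.6%) also passed between the low-low group and the other 3, all with the opposite sign. Without the low-low group, shortening was read at high stretch only: limma called 0 genes, with 360 at an unadjusted p under 0.05, and the Local Pooled Error test of the same 2 groups called 44 probe sets.

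In all, 12 fixed groups moved with cyclic shortening, each downward relative to the other genes. In oxidative phosphorylation 50 of 76 genes fell and 2 rose (Ndufa5 -1.59, Ndufb10 -1.15, camera adjusted p = 6.91e-13, and adjusted p = 0.194 with an estimated correlation). In the mitochondrial ribosome 35 fell and 13 rose (Mrpl52 -1.06, Mrpl54 -0.96, adjusted p = 0.000489, and adjusted p = 0.658 with an estimated correlation). In fatty acid oxidation 17 fell and 2 rose (Cd36 -1.71, adjusted p = 0.00103, and adjusted p = 0.571 with an estimated correlation). In glycolysis and hypoxia 18 fell and 2 rose (Adm, a vasodilator peptide induced by low oxygen, -1.60, Tpi1 -0.72, Gpi -0.70, adjusted p = 0.00066, and adjusted p = 0.194 with an estimated correlation). The contractile lists, which share genes such as Tnni3 and Myl2 and so are not independent, shifted too. Of 23 sarcomere genes 9 fell (Des -0.80, Myom1 -0.76, adjusted p = 0.0153, and adjusted p = 0.390 with an estimated correlation), as did 8 cardiomyocyte markers (Tnni3 -0.36, adjusted p = 0.0153, and adjusted p = 0.194 with an estimated correlation). In heat shock and protein folding 10 of 28 fell and 3 rose (Hsp90ab1 -1.41, Hspb7 -1.08, adjusted p = 0.0127, and adjusted p = 0.560 with an estimated correlation). In the proteasome 17 fell and 2 rose (Psmd6 -0.90, adjusted p = 0.000964, and adjusted p = 0.560 with an estimated correlation). In the cytosolic ribosome 17 fell and 3 rose (Rps24 -1.64, adjusted p = 0.00546, and adjusted p = 0.705 with an estimated correlation). In oxidative stress and NRF2 13 fell (Sod2 -0.69, Sod1 -0.37, adjusted p = 0.0123, and adjusted p = 0.390 with an estimated correlation). For cytokines and chemokines 14 fell and 1 rose (Ccl7 -1.09, Icam1 -0.83, adjusted p = 0.0118, and adjusted p = 0.705 with an estimated correlation). In the interferon response 7 fell (Psmb9 -1.08, Cd74 -0.66, adjusted p = 0.00997, and adjusted p = 0.705 with an estimated correlation).

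Adjusted over the list alone, these shortening falls numbered 52 in oxidative phosphorylation, 36 in the mitochondrial ribosome, 18 in fatty acid oxidation, 19 in glycolysis and hypoxia, 10 in sarcomere, 8 in cardiomyocyte markers, 10 in heat shock and protein folding, 17 in the proteasome, 18 in the cytosolic ribosome, 13 in oxidative stress and NRF2, 14 in cytokines and chemokines and 7 in the interferon response. Without the low-low group, with its Gapdh 3' excess of 0.54 log2 and labelled weight of 311, cytokines and chemokines passed in the opposite direction (Up, adjusted p = 0.00569, and 0.774 with an estimated correlation), heat shock and protein folding passed downward (0.0213, and 0.687 with an estimated correlation), and the other 10 did not pass. By fry neither passed (0.831 for both). Both calls also ended without high stretch high shortening replicate 1 (0.107 for both), high stretch low shortening replicate 1 (0.0707 and 0.193) or 2 (0.133 and 0.0737). In all 12 arrays, heat shock and protein folding did not pass for shortening at high stretch (0.0646). By fry, cytokines and chemokines (0.062) and the interferon response (0.0909) did not pass in all 12 arrays. Repeating quantile normalization ended the calls of cytosolic ribosome (adjusted p = 0.227), cardiomyocyte markers (0.420), sarcomere (0.337), heat shock and protein folding (0.114) and oxidative stress and NRF2 (0.0999). The 3' to 5' index as a covariate ended those of cytosolic ribosome (0.186) and oxidative stress and NRF2 (0.174). The call for cytokines and chemokines ended without low stretch high shortening replicate 2 (0.075) and with age as a covariate (0.0601), that for the interferon response without low-low replicate 3 (0.0782), and that for the cytosolic ribosome with age as a covariate (0.0582).

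The interaction, which asks whether the effect of shortening differs with the level of stretch, was the shortening effect at high stretch minus that at low stretch. The named positive genes, each higher in the low-low group than in the other 3, were Fabp4 at 5.48 log2 (SE 0.34, n = 12, adjusted p = 9.46e-07), or 4.52 with values under 4.91 log2 raised to it, the ATP synthase subunit Atp5mg at 5.06 (SE 0.45, adjusted p = 1.12e-05) and the complex I subunit Ndufb8 at 4.50 (SE 0.27). Pfn1 followed at 4.03 (SE 0.25) and Higd2a at 4.01 (SE 0.16, adjusted p = 7.6e-08). Hira at -4.02 (SE 0.28, adjusted p = 1.66e-06), the chromatin regulator Setd5 at -3.60 (SE 0.51, adjusted p = 0.000294), Ube3al1 at -3.59, Dhx36 at -3.29 and Nek1 at -3.28 were the named negative ones. With values so raised Hira gave -2.70 and Nek1 -2.20. Higd2a averaged 11.03 ± 0.13 log2 in the low-low group, against 7.31 ± 0.15 with high stretch and high shortening, 7.14 ± 0.02 with high stretch and low shortening, and 7.19 ± 0.08 with low stretch and high shortening (SD, n = 3 each). Limma called 3496 genes (1912 positive and 1584 negative, 1537 of at least 2-fold), and 1775 positive and 1775 negative after repeated quantile normalization. The calls of Atp5mg (3.27, adjusted p = 0.0628) and Setd5 (-2.81, adjusted p = 0.191) ended with the 3' to 5' index as a covariate.

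Of the fixed groups, 9 passed for the interaction, each upward. In oxidative phosphorylation 53 genes were positive and 1 negative (Ndufa5 3.06, camera adjusted p = 2.01e-14, and adjusted p = 0.155 with an estimated correlation). The positive and negative calls were 18 and 0 in cytokines and chemokines (Cxcl6 3.64, or 3.29 with values under 4.91 log2 raised to it, Ccl7 2.68, Nfkbia 2.45, adjusted p = 5.65e-05, and adjusted p = 0.754 with an estimated correlation). They were 19 and 0 in fatty acid oxidation (Cd36 3.36, Hadha 1.46, adjusted p = 5.65e-05, and adjusted p = 0.611 with an estimated correlation). Calls were 36 and 13 in the mitochondrial ribosome (Mrpl57 1.72, adjusted p = 0.000856, and adjusted p = 0.754 with an estimated correlation). In glycolysis and hypoxia they were 18 and 3 (Slc2a4 3.10, Adm 2.75, adjusted p = 0.00168, and adjusted p = 0.235 with an estimated correlation). The proteasome had 16 and 3 (Psmd6 1.71, adjusted p = 0.00519, and adjusted p = 0.754 with an estimated correlation). Oxidative stress and NRF2 had 12 and 0 (Txnrd1 2.02, Sod2 1.48, adjusted p = 0.00621, and adjusted p = 0.357 with an estimated correlation). Cardiomyocyte markers had 9 and 0 (Tnni3 1.12, adjusted p = 0.00621, and adjusted p = 0.155 with an estimated correlation) and the cytosolic ribosome 18 and 5 (Rps24 3.41, adjusted p = 0.019, and adjusted p = 0.754 with an estimated correlation). Adjusted over the list alone, positive calls were 55 in oxidative phosphorylation, 21 in cytokines and chemokines, 20 in fatty acid oxidation, 39 in the mitochondrial ribosome, 21 in glycolysis and hypoxia, 18 in the proteasome, 14 in oxidative stress and NRF2, 9 in cardiomyocyte markers and 18 in the cytosolic ribosome. Repeating quantile normalization ended the calls of cytosolic ribosome (0.524), proteasome (0.0724), oxidative stress and NRF2 (0.0769) and cardiomyocyte markers (0.369). The 3' to 5' index as a covariate turned cytosolic ribosome downward (0.641) and ended the calls of oxidative stress and NRF2 (0.722) and proteasome (0.310). That of the cytosolic ribosome also ended without high stretch high shortening replicate 1 (0.0561) or low stretch high shortening replicate 1 (0.0604). Among the genes named here, the index ended the calls of Cxcl6 (2.74, adjusted p = 0.0655), Nfkbia (1.52, 0.149), Hadha (0.87, 0.120), Adm (2.09, 0.080), Psmd6 (1.49, 0.0628), Txnrd1 (0.66, 0.460), Sod2 (1.62, 0.0602) and Tnni3 (1.04, 0.0822).

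Each input was also read at a single level of the other. At low shortening, high stretch went with lower Fabp4 (-5.60, SE 0.24, adjusted p = 1.51e-08), Atp5mg (-4.74), Ndufb8 (-4.22), Pfn1 (-4.22) and Higd2a (-3.89), and with higher Hira (3.92), Ube3al1 (3.56), Dhx36 (3.37), Ankrd11 (3.26) and Setd5 (3.15). At low stretch, high shortening went with lower values of the same 5 genes (Fabp4 -5.50, Atp5mg -4.39, Ndufb8 -4.14, Pfn1 -3.89, Higd2a -3.84). It went with higher Hira (4.17), Ube3al1 (3.47), Nek1 (3.31), Setd5 (3.18) and Dhx36 (3.13). Limma called 5152 genes (2414 higher, 2738 lower) for stretch at low shortening and 5051 (2477 higher, 2574 lower) for shortening at low stretch. Repeated quantile normalization turned these balances to 2700 higher and 2462 lower, and 2709 higher and 2342 lower. Both comparisons use the low-low arrays as their only baseline. With values under 4.91 log2 raised to it, Fabp4 gave -4.52 in both, Hira 2.6 for stretch and 2.85 for shortening, and Nek1 2.22 for shortening. The 3' to 5' index as a covariate ended the calls of Setd5, for stretch (2.44, adjusted p = 0.158) and for shortening (2.64, adjusted p = 0.0517). At high shortening, by contrast, limma called 0 genes for stretch, with 346 at an unadjusted p under 0.05 against 515.8 expected by chance. The smallest p-values there belonged to Fa2h (0.48, SE 0.12), Mcu, the pore of mitochondrial calcium uptake (-0.43, SE 0.11), the clock-controlled Hlf (-0.84, SE 0.22), Tg (0.40) and Aasdhppt (-0.46), each at an adjusted p of 1.00. At high stretch, 0 genes were called for shortening, with 392 at an unadjusted p under 0.05. The smallest p-values were those of Cflar, an inhibitor of caspase 8 (0.64, SE 0.13), Usp54 (-0.61, SE 0.13), Fnbp1 (-0.58), Flvcr1 (-0.67) and Kif3a (-0.67), each at an adjusted p of 1.00. The Local Pooled Error test, chosen after the data were seen, called 10 probe sets (3 higher, 7 lower) for stretch at high shortening and 44 (9 higher, 35 lower) for shortening at high stretch. In simulated data it called 62 of 10316 unchanged genes, whereas the real data held 16391 probe sets. Across the 10316 genes, which are not independent replicates, the stretch effects at high and at low shortening had r = 0.033, and the shortening effects at high and at low stretch r = -0.050.

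**Figure D2:**
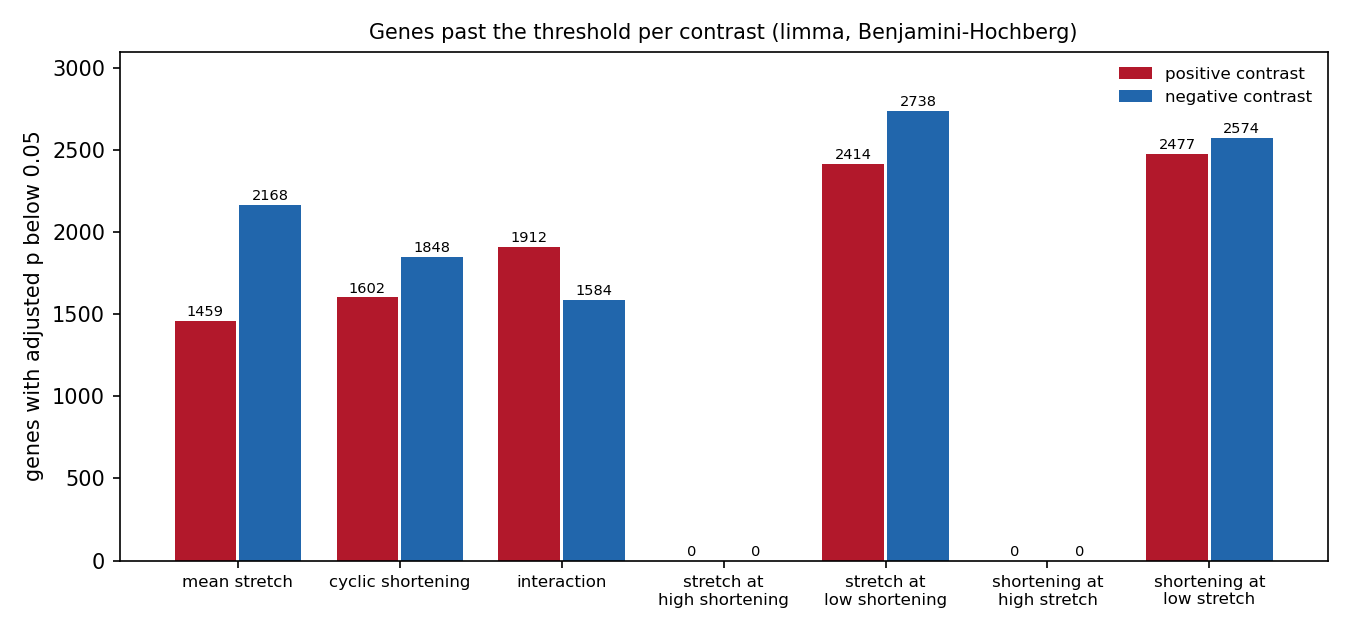
Number of genes past a Benjamini-Hochberg adjusted p of 0.05 in limma for each comparison, split into positive and negative differences, with the counts above the bars. The 5 comparisons that use the low-low group call 3450 to 5152 genes, and the 2 that do not call 0.

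Gene groups were also compared at the level where the low-low group enters only the estimate of the spread, a step chosen after the gene counts were seen. With stretch at high shortening, 20 of 23 genes of the interferon response lay below 0 (median -0.30, Mx2 -0.91, or -0.54 with values under 4.91 log2 raised to it, Stat2 -0.44, Ifi35 -0.31, none passing singly, camera adjusted p = 0.0163, and adjusted p = 0.919 with an estimated correlation). Genes of the extracellular matrix lay above 0 in 28 of 39 cases (median 0.11, Col6a2 0.55, SE 0.25, Fn1 0.44, SE 0.20, adjusted p = 0.0163, and adjusted p = 0.919 with an estimated correlation). The unfolded protein and amino acid response lay lower (median -0.09, Trib3 -0.66, SE 0.24, Herpud1 -0.38, SE 0.15, adjusted p = 0.0163, and adjusted p = 0.919 with an estimated correlation). So did the mitochondrial ribosome (median -0.07, Mrps31 -0.26, adjusted p = 0.0453, and adjusted p = 0.929 with an estimated correlation), whereas Schwann cell and neuronal markers lay higher (median 0.21, Ncam1 0.40, Th 0.21, adjusted p = 0.0325, and adjusted p = 0.919 with an estimated correlation). With shortening at high stretch, 36 of 41 cytokines and chemokines lay above 0 (median 0.20, Tnfaip6 0.68, SE 0.33, Lcn2 0.63, Nfkbia 0.42, SE 0.19, Il18 0.31, adjusted p = 0.00683, and adjusted p = 0.760 with an estimated correlation). Immediate early and MAPK feedback genes lay lower (median -0.14, Atf3 -0.89, SE 0.28, Fos -0.72, SE 0.32, Csrnp1 -0.52, Ier5 -0.40, adjusted p = 0.0237, and adjusted p = 0.760 with an estimated correlation). By fry, which tests whether the genes of a set move on balance one way without comparing them with other genes, 0 of 35 lists passed in either comparison, with adjusted p = 0.949 for the former 5 and 0.800 for the latter 2.

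Single arrays decided all of these calls. Without high stretch high shortening replicate 2 the interferon response gave an adjusted p of 0.506, and without low stretch high shortening replicate 1 0.471. The extracellular matrix call ended without high stretch high shortening replicate 3 (0.670), low stretch high shortening replicate 1 (0.118) or 3 (0.0832). That of the unfolded protein and amino acid response ended without high stretch high shortening replicate 1 (0.30) or 3 (0.112) or low stretch high shortening replicate 1 (0.118), and that of Schwann cell and neuronal markers without the same 3 arrays (0.0909, 0.112 and 0.146). The mitochondrial ribosome reached 0.836 without low stretch high shortening replicate 3. For cytokines and chemokines the call ended without high stretch high shortening replicate 1 (0.179) or high stretch low shortening replicate 1 (0.0816) or 2 (0.151). For immediate early and MAPK feedback it ended without high stretch high shortening replicate 2 (0.0668) or 3 (0.064) or high stretch low shortening replicate 1 (0.411) or 3 (0.174). For stretch at high shortening, weight as a covariate ended the calls of extracellular matrix (0.0781), interferon response (0.0843), unfolded protein and amino acid response (0.0843), mitochondrial ribosome (0.146) and Schwann cell and neuronal markers (0.0781). The 3' to 5' index as a covariate ended those of extracellular matrix (0.077), mitochondrial ribosome (0.483) and Schwann cell and neuronal markers (0.144). Repeating quantile normalization ended those of the mitochondrial ribosome (0.197) and Schwann cell and neuronal markers (0.0606), and array weights that of the unfolded protein and amino acid response (0.232). The filter mattered too: without it the extracellular matrix (0.133) and Schwann cell and neuronal markers (0.112) did not pass, and in the authors' filtered table the mitochondrial ribosome (0.11) and Schwann cell and neuronal markers (0.137) did not. For the mitochondrial ribosome the call also ended with the mean of probe sets (0.0602), with the replicate number as a block (0.063) and without the low-low group (0.056). For shortening at high stretch, the call of cytokines and chemokines ended with array weights (0.0647) and with the index (0.0912), and that of immediate early and MAPK feedback with array weights (0.0965) and with weight as a covariate (0.0934). With animal weight as a covariate the cytokine and chemokine call held (camera adjusted p = 3.9e-12). Its median went from 0.20 to 0.39 with weight and to 0.14 with the index, so the covariates moved it in both directions.

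Markers of the cell types that a papillary muscle holds were compared to see whether the tissue mix differed with either input. By camera, no cell-type list apart from the cardiomyocyte markers passed for stretch or for shortening. By fry, Schwann cell and neuronal markers also passed for stretch (adjusted p = 0.0114, upward), and fibroblast (0.0453) and smooth muscle and pericyte markers (0.0453) for shortening, downward. At low shortening, with the low-low group as baseline, more passed by fry for stretch. Endothelial (0.00954), fibroblast (0.0236), smooth muscle and pericyte (0.0409) and macrophage markers (0.0409) lay lower, and endocardial markers (0.00817) higher. None of these passed there by camera (0.195 to 0.590). Cardiomyocyte markers passed there downward by camera (0.0136) and by fry (3.47e-07), with 11 of 17 genes lower and 1 higher. Schwann cell and neuronal markers passed there upward by fry (0.00954) but not by camera (0.206). Fry passed 27 of 35 lists there, and 27 for shortening at low stretch. Among fibroblast markers Gsn (-0.93), Col1a2 (-0.97) and Col3a1 fell and Pdgfra, a receptor of resident fibroblasts, rose by 0.59 (SE 0.16, adjusted p = 0.0149) with stretch (3 of 14 lower, 1 higher, camera adjusted p = 0.807, and 0.292 for shortening). Of 15 endothelial markers 4 fell with stretch, among them Fabp4, Eng (-0.80) and Esam (-0.64) (0.614 and 0.309). Macrophage genes went both ways (C1qc -0.65, Tyrobp -0.63, Fcer1g -0.59, Laptm5 0.44, 5 of 16 lower and 1 higher, 0.807 and 0.580). Schwann cell and neuronal markers rose in 3 of 7 cases (Pmp22 0.60, SE 0.11, Dbh 0.35, Th 0.26, 0.069 and 0.698). Smooth muscle and pericyte markers had 2 falls among 11 (Mcam -0.88, Smtn -0.80, 0.656 and 0.0917). Atrial markers had 1 rise in Nppa and 1 fall in Myl4 (-0.69) among 9 (0.656 and 0.876), endocardial markers 1 rise in Nfatc1 (0.46) among 5 (0.185 and 0.515), and lymphocyte markers no call for stretch among 6 (0.807 and 0.576). Fewer than 5 genes were tested for the neutrophil (2), mast cell (1), erythrocyte (2), adipocyte (4), tendon and valve (4) and epicardial (3) lists, which were not analysed further.

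Most lists of mechanical and stress pathways did not pass by camera. For stretch the extracellular matrix had 2 genes higher and 6 lower of 39 (Sparc -1.52, Nid1 -1.16, Lama4 0.64, camera adjusted p = 0.922, median 0.01 but mean -0.10), YAP and SRF mechanosensitive targets 1 and 2 of 27 (0.807, median 0.05 but mean -0.01), and adhesion and cytoskeleton 3 and 9 of 39 (0.656). The higher and lower counts were 3 and 4 of 18 in cardiac stress and fetal genes (0.872), 1 and 8 of 23 in sarcomere (0.166), 3 and 6 of 31 in immediate early and MAPK feedback (0.922), 0 and 7 of 23 in matrix proteases and inhibitors (0.353), and 1 and 7 of 31 in growth factors and paracrine signals (0.807). Heat shock and protein folding had 3 and 9 of 28 (Hsp90ab1 -1.37, Hspb7 -1.19, Dnajb1 0.73, 0.166), the unfolded protein and amino acid response 4 and 11 of 38 (0.389), and calcium handling 2 and 6 of 25 (0.807). Potassium, sodium and gap junction channels had 2 and 2 of 26 (0.812, upward in camera with a median of -0.05), proteolysis and autophagy in atrophy 3 and 10 of 30 (0.614), apoptosis and p53 2 and 4 of 24 (0.922), cell cycle 3 and 1 of 24 (0.549), circadian clock 1 and 2 of 18 (0.993, upward in camera with a median of -0.01) and ribosome biogenesis and MYC targets 3 and 11 of 38 (0.172). By fry, which does not compare with other genes, falls on balance passed for stretch in proteolysis and autophagy in atrophy (adjusted p = 2.3e-05), sarcomere (0.000258), heat shock and protein folding (0.00162), matrix proteases and inhibitors (0.0221), apoptosis and p53 (0.0331) and the unfolded protein and amino acid response (0.0466). For shortening none of these lists passed by camera except sarcomere and heat shock and protein folding. By fry, proteolysis and autophagy in atrophy (7.31e-06), cardiac stress and fetal genes (0.00463), adhesion and cytoskeleton (0.0245), apoptosis and p53 (0.0285) and YAP and SRF mechanosensitive targets (0.044) also passed for shortening. Here the median and mean differed in sign for growth factors and paracrine signals (0.03 and -0.06), for cell cycle (-0.0075 and 0.02) and for the unfolded protein and amino acid response (0.05 and -0.15), and channels lay upward in camera with a median of -0.04.

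Among genes named beforehand for their known response to load, 15 were tested, and 2 passed for stretch, 2 for shortening and 2 for the interaction. Adjusted over the list alone the counts were also 2, 2 and 2. Nppa, the atrial natriuretic peptide, rose with mean stretch by 0.44 log2 (SE 0.09, n = 12, adjusted p = 0.00332). It averaged 6.87 ± 0.06 with high stretch and high shortening, 7.07 ± 0.08 with high stretch and low shortening, 6.64 ± 0.08 with low stretch and high shortening, and 6.42 ± 0.27 in the low-low group (SD, n = 3 each). All 6 high-stretch arrays (6.80 to 7.14) lay above all 6 low-stretch arrays (6.22 to 6.72). The rise was 0.65 at low shortening (adjusted p = 0.00133) and 0.22 (SE 0.13, adjusted p = 1.00) at high shortening, a difference that did not pass (-0.43, adjusted p = 0.0934) but did without low-low replicate 1 (-0.58, adjusted p = 0.013) and with array weights (-0.54, 0.0236). Leaving out any 1 array gave 0.39 to 0.52 with an adjusted p of 0.0006 to 0.0101. With the 3' to 5' index as a covariate the value was 0.43 and the call ended (adjusted p = 0.149). Nppa did not pass for shortening (0.01, adjusted p = 0.926).

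Nppb, the ventricular natriuretic peptide, changed with shortening by -0.57 log2 (SE 0.17, adjusted p = 0.02). It averaged 13.47 ± 0.12 in the low-low group against 12.53 ± 0.41, 12.67 ± 0.35 and 12.48 ± 0.36 in the groups with high stretch and high shortening, high stretch and low shortening, and low stretch and high shortening (SD, n = 3 each). Its call ended without high stretch high shortening replicate 2 (-0.49, adjusted p = 0.0516), on repeating quantile normalization (0.0549), without variance moderation (0.0551), and with weight (0.0565) or the index (0.0518) as a covariate. At high stretch its difference was -0.14 (adjusted p = 1.00). Nppb passed for stretch without high stretch high shortening replicate 3 (-0.49, adjusted p = 0.0288) or high stretch low shortening replicate 2 (-0.47, 0.0417). It passed for the interaction without high stretch high shortening replicate 2 (1.01, adjusted p = 0.0467), high stretch low shortening replicate 2 (1.06, 0.0274) or low stretch high shortening replicate 1 (1.06, 0.027), and with age as a covariate (0.94, 0.0475). Col3a1, a fibrillar collagen, changed with stretch by -1.18 (SE 0.29, adjusted p = 0.00745) and with shortening by -1.36 (SE 0.29, adjusted p = 0.00347), with an interaction of 2.49 (SE 0.57, adjusted p = 0.00547). It averaged 9.69 ± 0.29 in the low-low group and 7.16 ± 1.04, 7.27 ± 0.48 and 7.08 ± 0.18 in the other groups, in the same order. Weight as a covariate ended the Col3a1 calls for stretch (-1.25, adjusted p = 0.0543) and the interaction (0.107), and the index ended that for the interaction (4.23, adjusted p = 0.0708). Hspa1a, an inducible heat shock protein, had an interaction of -1.77 (SE 0.52, adjusted p = 0.0204). It averaged 10.86 ± 0.25 and 11.87 ± 0.22 at high stretch with high and low shortening, and 11.54 ± 0.65 and 10.78 ± 0.79 at low stretch. This call ended without low-low replicate 1 (-1.53, adjusted p = 0.0515) or 2 (-1.55, 0.0516), low stretch high shortening replicate 1 (-1.61, 0.0502) or 2 (-1.55, 0.0515), without variance moderation (0.0654), and with weight (-1.82, 0.225) or the index (-2.39, 0.277) as a covariate.

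The other 11 genes did not pass for stretch, shortening or the interaction. For stretch and shortening, the log2 differences were -0.19 and -0.21 for Myh7, the slow myosin heavy chain, -0.02 and -0.01 for Myh6, -0.09 and -0.44 for Acta1, the skeletal actin of the fetal programme, and -0.09 and -0.06 for the stretch-responsive Ankrd1. They were 0.18 and -0.33 for Fos, -0.11 and -0.13 for Egr1, 0.40 and -0.45 for Ccn2, 0.03 and -0.10 for Col1a1, -0.03 and 0.03 for Atp2a2, 0.07 and -0.18 for Trim63, and -0.07 and 0.10 for Tgfb2. Fbxo32 was not among the genes tested. Some alternatives did call them. With the 3' to 5' index as a covariate, Myh7 passed with its sign reversed for stretch (1.28, adjusted p = 0.0327) and the interaction (-3.27, 0.0413). In the authors' filtered table, which held its other probe set, Col1a1 passed for stretch, its sign reversed (-0.45, 0.0067), for shortening (-0.64, 0.000898) and for the interaction (1.19, 0.00129). With the mean of probe sets calls were made for Col1a1 (shortening -0.37, 0.0104, interaction 0.72, 0.0114), Myh6 (stretch -0.67, 0.000353, shortening -0.75, 0.000209, interaction 1.40, 0.000288) and Ankrd1 (stretch -0.30, 0.00471, interaction 0.48, 0.0157). Ankrd1 also passed for stretch without variance moderation (-0.09, 0.0382), and Egr1 with weight as a covariate (-0.51, 0.0364). Acta1 passed for shortening without high stretch low shortening replicate 3 (-0.61, 0.0299), and for the interaction without high stretch high shortening replicate 2 (1.23, 0.043) or high stretch low shortening replicate 2 (1.22, 0.0462). It also passed for shortening at low stretch (-0.92, adjusted p = 0.0242) and between the low-low group and the other 3 (0.67, adjusted p = 0.0341). Other probe sets of some of these genes differed: between the low-low group and the other 3, the probe set used for Myh6 shifted by 0.02 and the second by 2.80, those of Myh7 by 0.42 and 2.66, and those of Col1a1 by 0.13 and 1.12, the second averaging 4.64 to 4.83 log2, under the filter, in the other 3 groups. For Ankrd1 the shifts were 0.14 and 0.78 (adjusted p = 2.5e-05 for the second), and for Atp2a2 0.01 and, in the dimmest of its 4 probe sets, 1.02 (adjusted p = 0.00579).

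**Figure D3:**
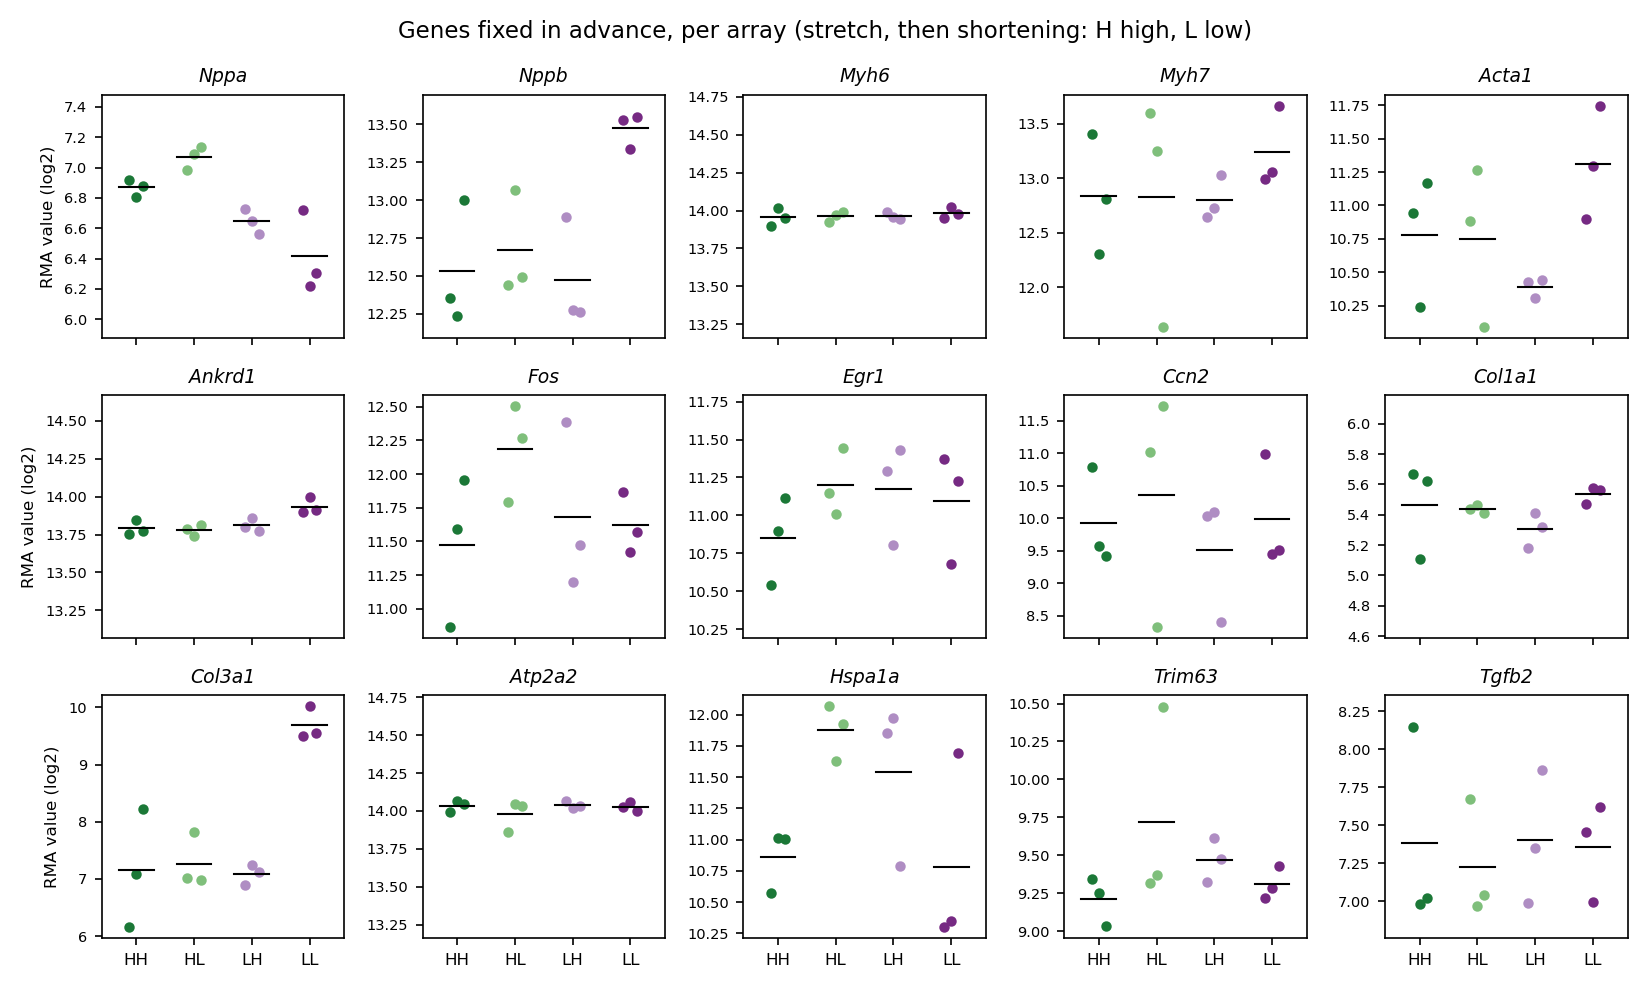
Log2 expression of genes fixed before the data were examined, by group; dots are the 3 arrays of a group and lines are means. Nppa is highest in the high-stretch groups (6.87 and 7.07), and Nppb and Col3a1 are highest in the low-low group (13.47 and 9.69).

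Differences among the 4 groups, tested by the moderated F statistic of limma, were called for 4816 genes, 46.7% of those tested. Between the low-low group and the mean of the other 3, a contrast chosen after the data were seen, 5939 genes passed (3032 higher and 2907 lower in the low-low group). Repeated quantile normalization turned this balance to 2705 higher and 3183 lower. Between the groups with a single high input, high stretch with low shortening and low stretch with high shortening, limma called 0 genes, with 614 at an unadjusted p under 0.05 and a smallest adjusted p of 0.720. Probe sets of 1 gene often parted in the low-low group. Of 2626 genes with several probe sets, both of the brightest 2 were called in 972, in the same direction in 576 and in opposite directions in 396 (40.7%, exact binomial 95% interval 37.6 to 43.9%). Dync1li1, a dynein subunit, had probe sets at -2.32 and 2.30, the splicing factor Srrm2 at -1.59 and 1.92, the clock-output gene Tef at 1.48 and -1.67 and the vesicle GTPase Rab14 at -2.46 and 1.18. The direction given for a called gene is therefore that of its brightest probe set.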

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

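Chosen only after the results were seen were the tests of additive effects, of a separate batch and of probe sets of 1 gene, the contrast of the low-low group with the other 3, the contrast of the groups with a single high input, the lists at a single level of the other input and the Local Pooled Error test.

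The interaction term of limma passed for 3496 genes. Of these, 3454 also passed between the low-low group and the other 3, all with the same sign. By camera the term passed for 9 gene lists, of which 0 passed with an estimated correlation (adjusted p = 0.155 to 0.754). The term does not tell a mechanical interaction from another source of the low-low shift. The named genes were Fabp4 (5.48 log2), Atp5mg (5.06), Ndufb8 (4.50), Pfn1 (4.03), Higd2a (4.01), Col3a1 (2.49), Hira (-4.02), Setd5 (-3.60), Ube3al1 (-3.59), Dhx36 (-3.29), Nek1 (-3.28) and Hspa1a (-1.77). In each, the mean of the low-low group was the highest or the lowest of the 4, although for Hspa1a it lay close to that with high stretch and high shortening (10.78 and 10.86). With the 3' to 5' index as a covariate the interaction calls of Atp5mg (3.27, adjusted p = 0.0628), Setd5 (-2.81, 0.191), Col3a1 (4.23, 0.0708) and Hspa1a (-2.39, 0.277) ended, the values of the last 2 having grown in size. With values under 4.91 log2 raised to it, Fabp4 gave 4.52, Hira -2.70 and Nek1 -2.20. Dixon's test for outliers was not applied to groups of 3; single arrays were assessed by leaving each out and by array weights, which ran from 0.445 to 2.25.

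The separation of the low-low group was weighed against technical and mechanical sources. A linear effect of the 3' to 5' index, scaled from its slopes among the other 9 arrays, projected on the shift of the group at -0.0747 (-0.0847 to -0.0622 on leaving out arrays), and one of weight at -0.0548 (-0.0681 to -0.0125), where 1 would account for the whole shift; both argue against a linear effect of the kind seen within those arrays, not against a larger step in RNA or labelling quality. The sum of the separate effects of stretch and shortening reached -0.011 (-0.0242 to 0.00213) of the shift, which argues against additive mechanical effects, and opposite calls in 40.7% of genes with 2 called probe sets argue against a change of whole-gene abundance alone (alternative transcript ends were not tested). A separate batch of animals, labelling or hybridization may underlie the shift and cannot be told apart from the group: 0 of the other arrays fell inside its range on the index, weight or the spread of log2 values, and the labels give no batch. A non-additive response to low stretch with low shortening stays open as untested.

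Each count of splits below includes the real split itself. As many genes were called in 1 of 100 splits for stretch (3627, highest other 3236), shortening (3450, highest other 3388) and the 4 groups (4816, highest other 4648). For the interaction 2 of 100 gave as many (3496, highest other 3566). Of the 100 splits, 2, with the real one, kept the 3 low-low arrays together and called 4648 and 4816 genes by the F-test. Splits that parted them called at most 1, which points to a structure of the samples. A share under 0.05 thus follows from 3 arrays that stand apart. It cannot exclude chance for an effect of stretch, of shortening or of their interaction. For the low-low group against the other 3, 1 of 100 splits gave as many calls (5939, highest other 833), but that group was singled out because its arrays stood apart, so this count excludes nothing. For lists chance cannot be excluded: 25 of 100 splits gave as many for stretch (10, highest other 12), 5 for shortening (12, highest other 14) and 39 for the interaction (9, highest other 16). With 3 arrays against 3 the 10 splits are too few for a share under 0.05. As many calls came from 1 split for stretch at low shortening (5152, highest other 0) and 1 for shortening at low stretch (5051, highest other 0). They came from all 10 for stretch at high shortening (0, highest other 1), shortening at high stretch (0, highest other 4) and the groups with a single high input (0, highest other 0). For lists they came from 6 splits for stretch at high shortening (5, highest other 13) and 10 for shortening at high stretch (2, highest other 9).

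List shifts at high stretch between high and low shortening may reflect RNA integrity, since the index averaged 2.94 and 3.77 in these groups. With the index as a covariate, the median of cytokines and chemokines was 0.717 of that without it (0.333 to 0.974 on leaving out arrays), and the call ended (adjusted p = 0.0912), which leaves this open. For immediate early and MAPK feedback the ratio was 1.82 (1.25 to 10.7), so the median did not shrink with the index. The fit is unstable, since leaving out 1 array moved this ratio to 10.7. It also called the cytosolic ribosome (camera adjusted p = 0.000231, and 0.733 without the index). RNA integrity is therefore left open here as well. A mechanical effect stays open as untested, and 1 array decided either call.

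For stretch at high shortening, the same ratio was 0.900 for the interferon response (0.870 to 1.39). It was 1.24 for the unfolded protein and amino acid response (0.716 to 1.47), so neither median shrank much with the index. The index averaged 2.94 and 3.21 in the groups compared, a small gap, and the fit was unstable. These ratios therefore do not decide whether RNA integrity took part. For the extracellular matrix the ratio was 0.282 (-1.55 to 1.08), which leaves RNA integrity open there too. A lower interferon response at high stretch may be mechanical or lie in the animals, both untested. With weight as a covariate the call ended (adjusted p = 0.0843) while the median went from -0.30 to -0.26, which favours neither. Of the cell-type lists only Schwann cell and neuronal markers passed at this level (median 0.21, adjusted p = 0.919 with an estimated correlation), and macrophage markers did not (median 0.05, adjusted p = 0.190).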

How the results depend on the processing

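Chosen only after the results were seen were the fits without the low-low group, the Local Pooled Error test, the raising of values under the filter to it, the lists at a single level of the other input and the contrast of the low-low group with the other 3, under every alternative.

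Without the low-low group limma called 0 genes for stretch, 0 for shortening and 0 among groups by F, with 304, 360 and 354 at an unadjusted p under 0.05, and camera 4 and 3 lists (0 and 0 with an estimated correlation, 0 and 0 by fry). Of named values past the threshold, 59 for stretch and 66 for shortening, 0 passed and 17 and 36 took the opposite sign; that these are given as counts was decided after they were seen. Leaving out that group also reads each input at a single level of the other and lowers the precision. With all 12 arrays kept, stretch at high shortening and shortening at high stretch also called 0 genes each. Their median absolute differences were 0.10 and 0.11 log2, against 0.42 and 0.41 at the low levels, where 5152 and 5051 genes passed. The median confidence interval reached 0.33 log2 to either side in all of these comparisons. This argues against lower precision alone for the gene calls. Leaving out the low-low group and reading a single level are the same step, so these were not told apart. Local Pooled Error called 10 and 44 probe sets for stretch at high shortening and shortening at high stretch. Testing every probe set gave 6252 for stretch, 5861 for shortening, 6015 for the interaction, 9033 and 8763 for stretch at low shortening and shortening at low stretch, 8294 by F and 10454 for the low-low group, more because more were tested. Weight as a covariate gave 2245 for stretch, 1156 for the interaction, 2261 and 2626 at the low levels, 1993 by F, 3058 for the low-low group, and 0 and 1 lists at high shortening and high stretch. The index as a covariate gave 1465, 737, 1342, 2020, 1663 and 2076 in the same order, and 13 lists for shortening at high stretch. For genes called for the interaction, the standard error rose 1.74-fold with weight and 2.36-fold with the index (medians) while the median value was 1.03 and 0.989 of that without it. Of the 3496, 9 and 192 took the opposite sign, and 191 and 701, these included, fell below 0.5 of their size. A minimum of 1.5-fold gave 1116 for stretch, 1015 for shortening and 3560 for the low-low group by construction. Camera with an estimated correlation called 0 lists in all 5 comparisons; fry called 17 for stretch, 18 for the interaction and 0 and 0 at the high levels. Repeated quantile normalization gave 7 lists for shortening, 5 for the interaction, 3 for stretch at high shortening and 4 for shortening at high stretch. It turned the balance of higher and lower genes in every comparison with calls except 2. Stretch became nearly even (1821 and 1816) and the interaction even (1775 and 1775). Shortening at high stretch had 4 lists with no filter, 5 with the mean of probe sets and 0 with array weights, and stretch at high shortening 3 in the filtered table; the cause was not tested. Reversed values were Col1a1 for stretch in the filtered table (-0.45, adjusted p = 0.0067), where another probe set represents it, and, with the index as a covariate, Myh7 for stretch (1.28, adjusted p = 0.0327) and the interaction (-3.27, adjusted p = 0.0413), whose cause was not tested. Of 192 named values past the threshold among 298, the index ended 37, weight 7, no moderation 2, and repeated quantile normalization and the mean of probe sets 1 each; the replicate block, age, array weights, trended prior, filtered table and no filter ended 0. Leaving out 1 array gave 3048 to 3544 genes for stretch, 2921 to 3444 for shortening, 2964 to 3428 for the interaction, 0 to 0 for stretch at high shortening, 4539 to 5291 at low shortening, 0 to 0 for shortening at high stretch, 4394 to 5176 at low stretch, 3845 to 4943 by F, 5171 to 5954 for the low-low group and 0 to 1 between the groups with a single high input (1 without high stretch low shortening replicate 3). Lists ranged over 9 to 11 for stretch, 12 to 14 for shortening, 8 to 10 for the interaction, 0 to 6 for stretch at high shortening (0 without low stretch high shortening replicate 1, 2 without high stretch high shortening replicate 1 or 3) and 2 to 7 for shortening at high stretch (7 without high stretch low shortening replicate 3, 6 without high stretch high shortening replicate 2). Probe sets with a mean under 4.91 log2 were removed, so changes among the dimmest were not tested. Raising array values under 4.91 to it ended 0 of the 192 calls but moved the interaction of Fabp4 from 5.48 to 4.52, of Hira from -4.02 to -2.70 and of Nek1 from -3.28 to -2.20.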

Other observations

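The relation of gene span to the shifts was computed only after the results were seen. Genomic span in the RefSeq table was known for 10309 genes (99.9%). In the fifth of genes with the shortest span, the median shift of the low-low group was 0.14 log2 (828 genes higher and 404 lower), and in the fifth with the longest it was -0.12 log2 (436 higher and 666 lower). Across genes, which are not independent replicates, Spearman's rho between span and that shift was -0.161; it was -0.052 for stretch at high shortening and -0.15 for shortening at high stretch.

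The Local Pooled Error test was also run on all 10 splits of each pair of groups, too few for a share under 0.05. For stretch at high shortening the real split gave 10 probe sets and the highest other 71; for shortening at high stretch the values were 44 and 160. For stretch at low shortening they were 6155 and 664, and for shortening at low stretch 7027 and 672.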
